A study of Drosophila melanogaster with 12 samples.

How the data were processed

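Whole-body total RNA of virgin flies aged 4 days was profiled in Drosophila melanogaster from 6 experimentally evolved populations, 3 kept under monogamy and 3 under polygamy for 65 generations, per the labels' protocols. Each population gave 1 male and 1 female sample, so that 12 single-colour NimbleGen arrays formed 4 groups of 3. The RNA was extracted with RNAzol and labelled with Cy3 at a facility approved by the array's maker, per the labels. The populations are separate per the labels, so a p-value measures the spread between populations together with that of single arrays. RNA-Seq of heads, which the series also describes, was not analysed here.

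The deposited values are log2 expression values, 1 per transcript and array, made with RMA per the submitters' processing notes. The software version, the annotation release and the arrays that were normalized together are not given in the sources used here. The quantiles of the 12 columns differed, so the columns as deposited do not share 1 distribution. The table holds 16637 transcripts under FlyBase transcript identifiers, and all 12 columns were matched to a sample. No detection calls were used here. Arrays have no read depth: the number of arrays limits the precision.

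The deposited table pairs no identifier with a gene. A RefSeq gene table of assembly Release 6 paired 44 of the identifiers with a gene symbol, 16 with 1 gene and 28 with several genes on 1 transcript. The value of a transcript with several genes cannot be assigned to either gene, and such transcripts are given with all their symbols. The unit of every test was therefore the transcript, although genes had been planned. None of the members of 22 gene lists fixed before the data were examined (reproductive tissues, immunity, metabolism, other tissues of the fly) was among the matched genes: the number was 0, and no list could be tested. Coordinates are not given, because the annotation behind the deposited identifiers is not given.

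No filter or further normalization was applied in the main setting. Transcripts were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on log2 values, in 1 fit of the 4 groups over all 12 arrays, without a block. The comparisons were monogamy minus polygamy in males and in females, male minus female averaged over the regimes, and the interaction of sex and regime. For the regime difference averaged over the sexes, the male and female values of each population were averaged first. All p-values were adjusted by the Benjamini-Hochberg method over all transcripts, with a threshold of 0.05, and the sex difference also needed an absolute log2 difference of at least 1. Transcripts past both thresholds formed the male-biased and female-biased classes. Their regime difference was tested with camera, with a preset correlation of 0.01 and with an estimated correlation, and with fry. A sex index per array, the mean log2 value of the female-biased class minus that of the male-biased class, was compared between regimes with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 arrays against 3.

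Before the data were examined, a rule for the genes to be named was fixed, and it was adapted because few identifiers had a gene symbol. Among transcripts past the threshold whose groups did not overlap, up to 10 with a gene symbol were named in each direction by size of difference, plus 2 with a CG number. Where no named transcript passed, the 5 smallest unadjusted p-values in each direction were used and are stated as not passing. The rule as first fixed did so only where nothing passed. Its use for regime in females, where 10 transcripts without a name passed, was part of the adaptation. Up to 2 identifiers without a name are given per direction, which the first rule did not include.

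Male and female samples of 1 population share its subject label, which pairs them. As a check, deviations from the group means correlated between male and female at 0.53, -0.07 and 0.40 in the monogamy populations and at 0.09, 0.07 and -0.18 in the polygamy populations, and 4 of the 12 arrays correlated best with their own population in the other sex. Each array was set against the 3 populations of its regime, so 4 of 12 is the number that chance gives. Fits with the population as a block, fixed or random (statmod 1.5.0), were alternatives. The others were quantile normalization over all arrays or within each sex, centring on the median, leaving out dim transcripts, another eBayes prior, other thresholds, fits of 1 sex or 1 regime, other sex-bias classes, and leaving out each array in turn. Cyclic loess within each sex, raising values below the 5th percentile of their array to it, and leaving out 2 or 3 arrays together were added after the data were seen.

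The fits were tested on simulated values of 16637 transcripts, of which 100 were changed by 1 and 100 by 2 on the log2 scale. Each transcript had 1 mean for all arrays and independent noise at the spread of the fit, pooled over the 4 groups. At an adjusted p under 0.05, the male regime comparison recovered 2% of the changes of 1 and 51% of the changes of 2. The female regime comparison recovered 1% and 32%, and the sex difference 21% and 78%. False calls numbered 0, 0 and 11. The simulated sex calls used the adjusted p alone, without the log2 difference of at least 1 that the sex calls in the data also needed. The simulated spread was the same in both sexes, so the gap between 51% and 32% within the simulation reflects random draws. For the same reason, the simulation cannot tell whether power was equal in the data. There, polygamy female 3 correlated at only 0.733 with the other females, so the recovered shares need not carry over. Correlation between transcripts was not simulated, so the false calls need not carry over to the data.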

Results

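Gene expression was measured on arrays in whole virgin males and females from 3 populations of Drosophila melanogaster evolved under monogamy and 3 evolved under polygamy, with 1 array per population and sex (n = 3 in each of 4 groups). Monogamy removes competition between males for mates and choice among them, and the design asks how expression differs between the regimes, in each sex, and whether transcripts with sex-biased expression shift together. Values are log2 expression values as deposited, for 16637 transcripts.

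The sexes separated on the first principal component, which held 69.8% of the variance. The deposited values of polygamy female 3 stood apart from the other arrays. Its 5th percentile was 5.42, against 4.30 to 4.43 in the other females, and its mean correlation with the other females was 0.733, against 0.894 to 0.924. The 10% of transcripts with the lowest levels in the other females lay a median of 2.49 higher in it, and the 10% with the highest levels differed by -0.37. The most similar arrays, monogamy male 3 and polygamy male 3, correlated at 0.994 and differed by a median of 0.14 per transcript, so no array repeated another.

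**Figure D1:**
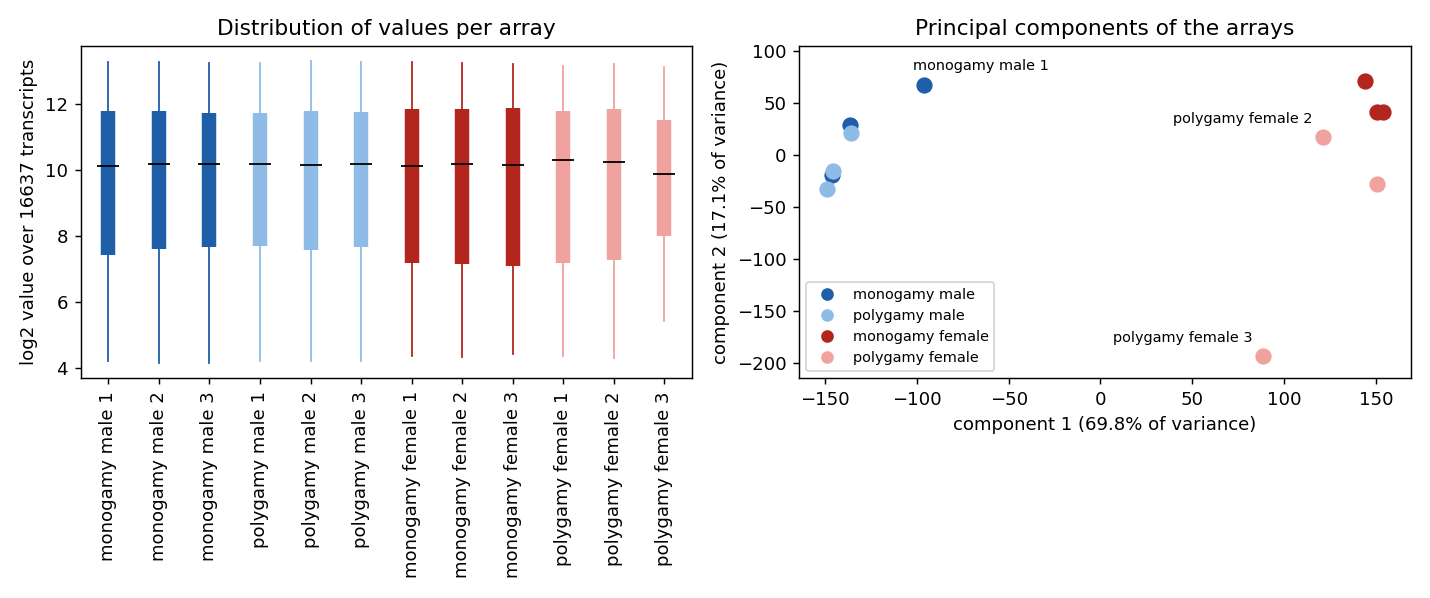
Left, log2 values of all transcripts per array, with the median (black line), the 25th to 75th percentiles (thick bar) and the 5th to 95th percentiles (thin line). Right, scores of the 12 arrays on the first principal components, with 69.8% and 17.1% of the variance. Polygamy female 3 has the narrowest distribution and lies at -193.6 on the second component.

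Some arrays also differed in transcripts of the other sex. For each array, transcripts were taken whose median was under 5 in the other 5 arrays of its sex and over 10 in the opposite sex. The excess of the array was taken over that median of the other 5. In polygamy female 2, 348 such male-limited transcripts had a median excess of 1.15, while 684 transcripts low in both sexes differed by -0.27. Of the 348, 17.5% lay above every other female, polygamy female 3 included, against 16.7% by chance. In monogamy male 1, 39 female-limited transcripts lay a median of 3.36 above the other males, and 705 transcripts low in both sexes lay 0.18 above. In polygamy female 3 both sets were raised, by 3.02 and 2.32.

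**Figure D2:**
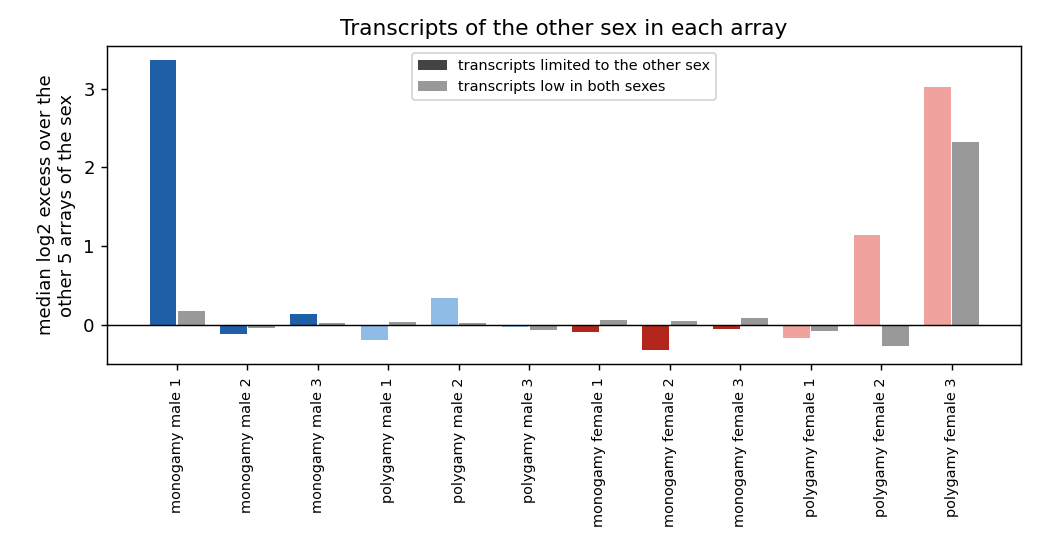
Median log2 excess of each array over the median of the other 5 arrays of its sex, for transcripts limited to the opposite sex (coloured bars, by group) and for transcripts low in both sexes (grey bars). Monogamy male 1 reaches 3.36 and polygamy female 2 reaches 1.15 in the first set, against 0.18 and -0.27 in the second. Polygamy female 3 is raised in both sets.

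Sex was the first comparison, which asks which transcripts differ between males and females whatever the regime. Among transcripts with a name, CG31178 was higher in males by 6.60 on the log2 scale (SE 0.54, adjusted p = 2.25e-06), with 11.33 ± 0.98 in males and 4.73 ± 1.14 in females (SD, n = 6 each). In polygamy female 2 it stood at 7.04, and in the other 5 females at 4.52 or lower, below the 5th percentile of each array, so that the size of its difference is uncertain. With values below that percentile raised to it, the difference was 6.34. Fatp1, a fatty acid transport protein, was higher in males by 1.16 (SE 0.37, adjusted p = 0.0211), with 13.47 ± 0.17 against 12.31 ± 1.13 (SD, n = 6 each). Without polygamy female 3 the difference of Fatp1 was 0.78, below the required size of 1. Wdr24, a subunit of a complex that regulates the TORC1 growth pathway, was higher in females, with a difference of -2.29 (SE 0.21, adjusted p = 6.30e-06) between 8.79 ± 0.38 in males and 11.09 ± 0.21 in females (SD, n = 6 each).

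On transcripts that carry several genes, 4 more passed by the same rule, all higher in females. The transcript of Rad1, a DNA damage checkpoint protein, and Sws1 differed by -2.95 (SE 0.39, adjusted p = 9.85e-05). That of Mocs2A and Mocs2B, subunits of the enzyme that makes molybdopterin, differed by -2.24 (SE 0.27, adjusted p = 5.11e-05). That of moi, a telomere capping protein, and Tgs1, which modifies the cap of small RNAs, differed by -1.45 (SE 0.18, adjusted p = 6.85e-05). That of PIG-P, of glycolipid anchor synthesis, and Tcs6, of transfer RNA modification, differed by -1.07 (SE 0.21, adjusted p = 0.00137), and fell short of the required size without polygamy female 3 (-0.91) and without polygamy male 3 (-0.99).

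Of the 44 transcripts with a name, 2 were higher in males, 12 were higher in females and 30 were neither. The 7 others that were higher in females overlapped between the sexes in at least 1 array and were chosen for mention after their values were seen. They were SuUR, which suppresses replication in late-replicating chromatin (-2.30), rdx, an adaptor of a ubiquitin ligase (-2.16), fend (-1.30) and NaPi-III, a phosphate transporter (-1.12), and the shared transcripts of CG42516 and Pbp49 (-1.60), of Polr3K and Tcs1 (-1.15) and of CG7950 and Rpp14a (-1.12). His4r, a histone (-0.27), Uba1, the ubiquitin-activating enzyme (-0.12), and alpha-Spec, a spectrin of the membrane skeleton (0.61), did not pass.

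**Figure D3:**
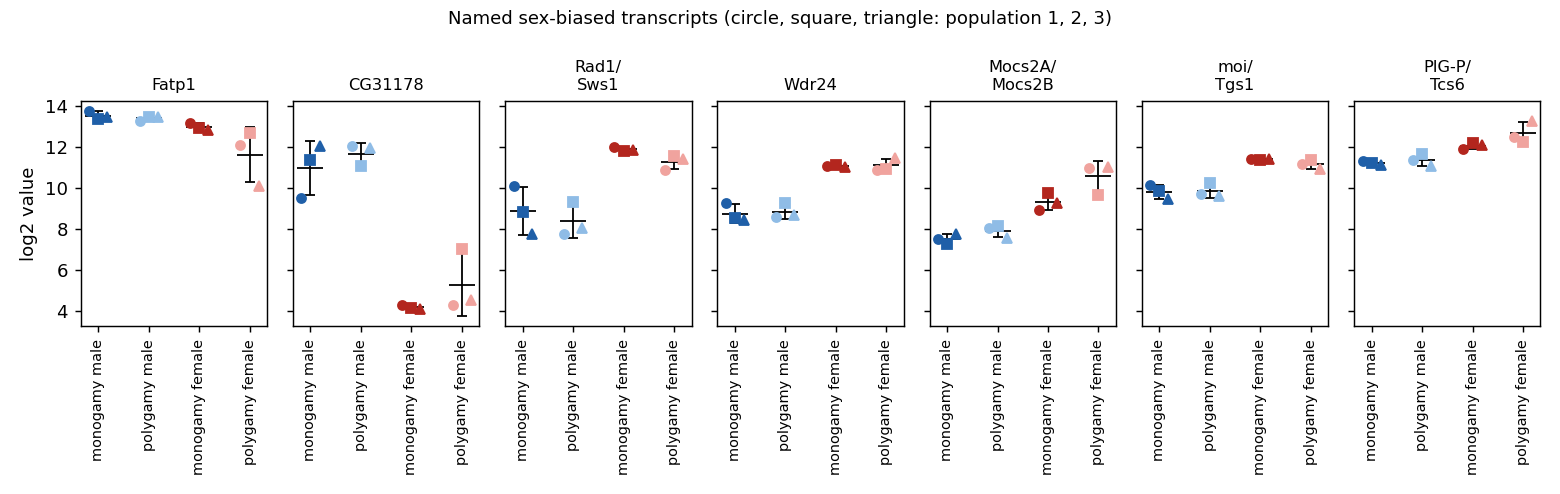
Log2 values of the named transcripts past the sex threshold, per array, in the 4 groups. Symbols give the population (circle 1, square 2, triangle 3), horizontal lines the group mean and error bars the SD (n = 3). CG31178 is at 4.52 or lower in 5 females and at 7.04 in polygamy female 2, and Fatp1 is at 10.12 in polygamy female 3.

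Over all transcripts, 7062 (42.4%) passed, of which 2728 were higher in males and 4334 in females (limma, adjusted p under 0.05 and an absolute log2 difference of at least 1). The balance turned with the size of the difference. At a log2 difference of at least 2 there were 1973 higher in males and 1463 in females, at 4 there were 1328 and 202, and at 6 there were 393 and 37, so that males held 91.4% of the last set. The extreme unnamed transcripts were FBtr0073182 (7.95) and FBtr0087420 (7.89) on the male side, of which 5 and 3 female values lay below the 5th percentile of their arrays (7.23 and 7.55 with these raised to it). FBtr0087420 stood at 8.02 in polygamy female 2 and at 4.74 or lower in the other females, and without that array its difference was 8.57 and that of FBtr0073182 was 8.27. On the female side they were FBtr0076573 (-8.14) and FBtr0081241 (-7.52). Within polygamy alone 4548 passed, with 2171 higher in males, and within monogamy alone 6844 passed, with 2469 higher in males. Each count came from a separate fit of 6 arrays, and the polygamy fit held polygamy female 3, whose values stood apart. The 2 counts therefore do not show that sex bias differs between the regimes.

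**Figure D4:**
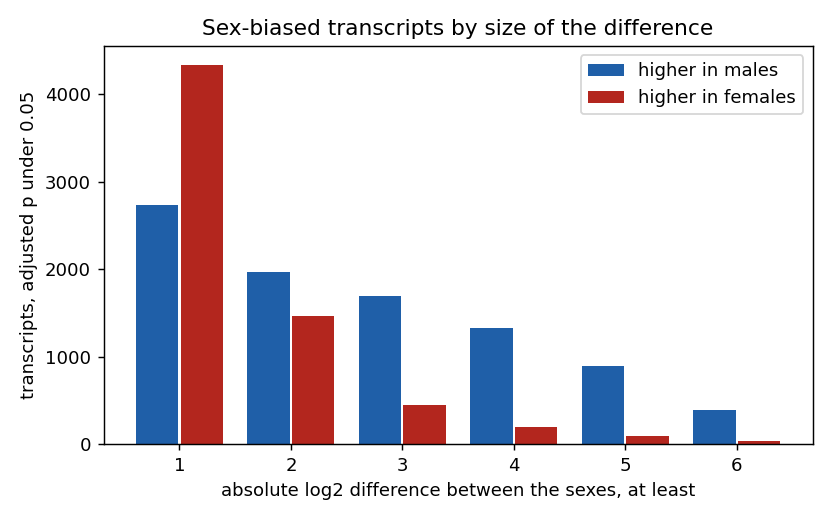
Number of transcripts at an adjusted p under 0.05 that were higher in males (blue) or in females (red), for each minimum absolute log2 difference. Females hold more transcripts at a minimum of 1 (4334 against 2728), and males hold more from 2 upward.

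In males, the comparison of regimes asks how expression evolved in the sex that competes for mates. No transcript passed (0 of 16637, limma). At an unadjusted p under 0.05 there were 220, with 148 higher and 72 lower under monogamy, where 832 are expected by chance. The fit shares 1 spread per transcript over all groups, so the spread of the female arrays also entered these p-values. Without polygamy female 3, 683 were at that level in males. With the male arrays fitted alone, 0 passed as well. The median absolute difference was 0.23. The named transcripts with the smallest unadjusted p-values did not pass, with adjusted p-values near 1. The difference of sle, a nucleolar protein needed in brain development, was -1.77 (SE 1.12), between 8.43 ± 2.11 under monogamy and 10.21 ± 1.77 under polygamy (SD, n = 3 each). LanA, a laminin of basement membranes, differed by -0.85 (SE 0.59) and HDAC3, a histone deacetylase, by 0.21 (SE 0.30). Shared transcripts ranged from -1.14 for CG42516 and Pbp49 to 0.51 for Rad1 and Sws1, with -0.86 for CG42497 and Tim10, -0.57 for CG30100 and CG42372, 0.50 for CG32573 and CG42512, 0.47 for Polr3K and Tcs1 and 0.20 for CG42374 and Mettl5. Chance gives on average 10% of transcripts whose groups do not overlap, and 7.75% were found.

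In females, the same comparison found 10 transcripts, all lower under monogamy and none with a name. FBtr0073671 differed by -4.35 (SE 0.53, adjusted p = 0.0207), between 3.60 ± 0.05 under monogamy and 7.95 ± 0.52 under polygamy, and stood at 12.68 and 13.23 in males of the 2 regimes (SD, n = 3 each). FBtr0112429 differed by -4.21 (SE 0.50, adjusted p = 0.0207), between 3.47 ± 0.63 and 7.68 ± 0.91. All 3 monogamy values of both transcripts lay below the 5th percentile of their arrays, so that the sizes are uncertain, and with values below that percentile raised to it the differences were -3.57 and -3.30. Both calls were lost, at differences of -3.68 or larger in size, after quantile normalization (adjusted p = 0.0566 over all arrays and 0.0855 within each sex), after cyclic loess within each sex (adjusted p = 0.112) and without monogamy female 1 or 2 (adjusted p = 0.142 and 0.139). That of FBtr0073671 was also lost without monogamy female 3 (adjusted p = 0.103). All 10 were lower in each monogamy female than in each polygamy female. The number at an unadjusted p under 0.05 was 4824 (29.0%), with 2684 higher and 2140 lower, and 38.2% of transcripts did not overlap between regimes, against 10% by chance on average. Transcripts are not independent, so a single grouping can lie far from 10% without a regime difference.

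Named transcripts did not pass in females. Under monogamy kis, a chromatin remodeller, differed by -1.36 (SE 0.45, adjusted p = 0.125), between 9.77 ± 0.22 and 11.13 ± 0.81 (SD, n = 3 each). NaPi-III differed by -1.19 (adjusted p = 0.125), Fatp1 by 1.35 (adjusted p = 0.141) and mio, of the same complex as Wdr24, by 1.02 (adjusted p = 0.169). Polygamy female 3 held the lowest female value of Fatp1 and of mio, 10.12 and 9.03. Differences of shared transcripts were 1.75 for CG32573 and CG42512, 1.31 for Polr3K and Tcs1, 0.78 for CG42488 and CG5116, -1.24 for Mocs2A and Mocs2B, -1.26 for CG30100 and CG42372 and -1.81 for CG42497 and Tim10. The count of 10 depended on single arrays and on the fit. It was 2080 without polygamy female 2, with 1328 higher and 752 lower under monogamy, and 201 without polygamy female 1, with 5 higher and 196 lower. It was 1 without monogamy female 1 or 2, 4 without monogamy female 3, 1 after quantile normalization, 4 after cyclic loess within each sex and 0 when the 6 female arrays were fitted alone.

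Averaged over the sexes, with the population as the replicate, no transcript was shown to differ between regimes (0, limma). At an unadjusted p under 0.05 there were 2511, with 1145 higher and 1366 lower under monogamy, and the smallest adjusted p was 0.318. The regime difference was also not shown to differ between the sexes for any transcript (0, limma, smallest adjusted p 0.0622), and 593 interactions were at an unadjusted p under 0.05. Without polygamy female 1 there were 7. The named transcripts with the smallest p-values did not pass, at an adjusted p of 0.862: the interaction was 1.39 for kis, 1.57 for rdx, 0.77 for NaPi-III, -1.22 for Fatp1 and -0.95 for mio. For shared transcripts it was 0.83 for Mocs2A and Mocs2B, 0.57 for CG45089 and ND-MNLL, -0.37 for CG7071 and Muted, -0.62 for CG42488 and CG5116 and -1.25 for CG32573 and CG42512.

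Across transcripts, the regime differences of males and females correlated (Pearson r = 0.649, Spearman rho = 0.671), and 76.8% had the same sign. Transcripts are not independent replicates. Over the 10 splits of the 6 populations into 3 and 3, the highest other correlation was 0.490, and 10 splits cannot give a share below 0.1. Without monogamy male 1 the correlation was 0.303.

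Sex-biased transcripts were compared between the regimes to ask whether they shift together under monogamy. In males, the 2728 male-biased transcripts had a median difference of -0.14, the 4334 female-biased transcripts 0.08 and all others 0.04. The preset correlation of camera gave an adjusted p of 2.18e-07 for the male-biased and 0.0248 for the female-biased class. Neither passed with an estimated correlation (adjusted p = 0.277 and adjusted p = 0.401), and the p of fry was 0.394 and 0.639. The sex index was -3.11 ± 0.52 under monogamy and -3.42 ± 0.15 under polygamy (SD, n = 3 each, exact permutation p = 0.6). Monogamy male 1, whose female-limited transcripts were raised, had an index of -2.52, and the other males had -3.25 or lower. Without it, the median of the female-biased class less that of the male-biased class went from 0.22 to -0.01.

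In females, the male-biased transcripts had a median difference of -0.52, the female-biased transcripts 0.03 and all others 0.18. The mean of the female-biased class was -0.10, opposite in sign to its median, and camera placed the class lower than the other transcripts. With the preset correlation the male-biased class had an adjusted p of 5.94e-05 and the female-biased class 0.233, and with an estimated correlation neither passed (adjusted p = 0.464 and adjusted p = 0.650). The p of fry was 0.188 for the male-biased and 0.774 for the female-biased class, and for change in either direction 0.0246 and 0.0634. The sex index was 2.65 ± 0.09 under monogamy and 2.25 ± 0.49 under polygamy (SD, n = 3 each, exact permutation p = 0.4). Male-biased transcripts averaged 7.05 in polygamy female 1, 7.46 in polygamy female 2 and 8.25 in polygamy female 3, and 7.03 to 7.17 in the monogamy females. The class difference of 0.55 was 0.28 without polygamy female 3 and 0.05 without polygamy females 2 and 3. It was 0.29 and 0.26 after quantile normalization over all arrays and within each sex, 0.13 after cyclic loess within each sex, where the median of the female-biased class was -0.07, and 0.32 with classes by adjusted p alone.

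**Figure D5:**
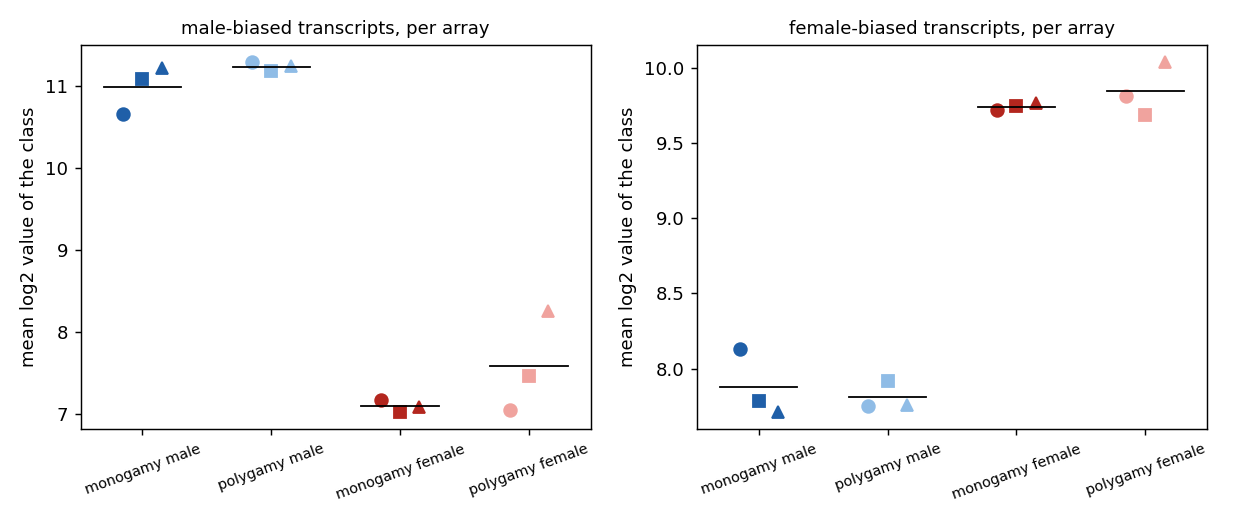
Mean log2 value of the male-biased class (left) and of the female-biased class (right) in each array, by group. Symbols give the population (circle 1, square 2, triangle 3) and horizontal lines the group mean (n = 3); the vertical axes do not start at 0. Monogamy male 1 and polygamy females 2 and 3 lie away from the other arrays of their sex in the male-biased class.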

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

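The tests of technical explanations in this part were chosen after the patterns were seen, and of these the cyclic loess test was fixed before its own result was seen. Within the 6 arrays of a sex, an array was singled out when its gap to the nearest other array, divided by the range, exceeded Dixon's critical value for 6 values. Of 62 sets of 6 values, 12 contained such an array, and chance gives about 1 in 20 for a single set. The sets are drawn from the same arrays and are not independent, so their number is not a test. In monogamy male 1 these were the mean correlation with the other males (0.925), the sex index (-2.52) and the mean of the male-biased class (10.65). In polygamy female 3 they were the 5th, 25th and 75th percentiles (5.42, 7.9994 and 11.50), the mean correlation with the other females (0.733), the means of the male-biased (8.25) and the female-biased class (10.04), Fatp1 (10.12) and mio (9.03). In polygamy female 2 it was CG31178 (7.04).

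Polygamy female 3 had raised dim transcripts. Male RNA alone is argued against, since transcripts low in both sexes also rose, by a median of 2.32, which a male share would not bring. A raised background of dim transcripts stays open. The 10% of transcripts with the lowest levels lay 2.49 higher and the 10% with the highest differed by -0.37, but this is the pattern itself and cannot test its cause. Shifts also varied among transcripts of like level. Their quartiles were 1.01 and 3.79 in the lowest 10%, and -1.49 and 0.23 in the 10% with a median level of 11.79. Whether the shift of dim transcripts accounts for the correlation of 0.733 with the other females was not tested. No biological explanation was tested, and a difference of this population stays open.

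Transcripts limited to the other sex were raised in polygamy female 2 and in monogamy male 1. In polygamy female 2 the rise followed the level in males (Spearman 0.823 over 348 transcripts, which are not independent), at a median of 1.02% of the male level, and transcripts low in both sexes did not rise (-0.27), which argues against a raised background and is consistent with a small amount of male RNA in that sample. In monogamy male 1 the rise also followed the level in females (Spearman 0.513), at a median of 11.2% of it, but RNA of whole females at 1 share as the whole cause is argued against: of 39 female-limited transcripts, 10 were under 1% of the female level and 21 were over 10%, up to 44.1%, and the upper quartile of the share was 19.9 times the lower, against 2.54 times in polygamy female 2. Transcripts low in both sexes rose in monogamy male 1 by a median of 0.18, which argues against a raised background as the whole cause. A small rise of the background stays open, since 42.0% of them lay above all other males, against 16.7% by chance. RNA from part of a female, a smaller share of female RNA beside another source, and a real difference of that population also stay open, untested.

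In females, 4824 transcripts were at an unadjusted p under 0.05 between regimes. Polygamy female 3 alone is argued against, since 4101 were at that level without it. Leaving it out also changed the spread shared with males, where the number went from 220 to 683, so its part is not known. With the female arrays fitted alone, 3601 were at that level. Scaling that depends on level as the whole cause is also argued against, since 4946 were at that level after cyclic loess within each sex. Of the 10 calls, 3 were kept after it and 7 were lost, whose median difference was -2.97 before (median SE 0.42) and -2.59 after (median SE 0.54), with a larger SE in all 7 and a smaller difference in 6. Among males of the same regime, 1 axis held 81.7% of the variance, and over transcripts this axis, defined without females and without the regime difference, correlated with the female regime difference at 0.633, against at most 0.466 in size for the other 9 splits. Variation between samples that is not tied to mating regime may therefore have contributed to the female difference. An effect of regime along the same axis stays open, because the scores of the female regimes did not overlap (exact permutation p = 0.1, the smallest possible).

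In a fit with sex and regime as separate terms, 100 of 462 possible splits of the 12 arrays were drawn. Only the real one gave as many sex-biased transcripts, with 7098 against 3371 for the highest other. The splits did not keep the pairing of male and female within a population. A share of 1 in 100, the smallest these draws can give, argues against chance for that count but does not exclude it. The 10 splits of the 6 populations are too few for a share under 0.05. The real value was 10 in females (highest other 0, 1 split with as many), 0 in males (highest other 7, 10 splits with as many), 0 averaged over the sexes (highest other 0) and 0 for the interaction (highest other 0). In males, the split of monogamy 1, monogamy 2 and polygamy 2 from the rest gave 7 transcripts and 3540 at an unadjusted p under 0.05, against 220 for the real split, which points to a structure of the male samples other than regime. In females the real split gave the most at that level, 4824, against 267 to 1833 for the other 9.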

How the results depend on the processing

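Cyclic loess, a floor at the 5th percentile of each array and settings that leave out 2 or 3 arrays at a time were chosen after the data were seen; all others before. The count for regime in males and that averaged over the sexes were 0 under every alternative run. The sex difference counted 6636 to 7451 without single arrays and 7088 with the replicate block of population, which shared 6962 transcripts with the 7062, lost 100 and gained 126; it was 3436 at a log2 difference of at least 2 and 4548 within polygamy alone. The count of 10 in females was 1 with either quantile normalization, 4 after cyclic loess, 0 with the 6 female arrays alone, 18 at an adjusted p under 0.1, and 1 to 2080 without single arrays (1328 higher and 752 lower in the last); without polygamy female 3 it was 10, of which 6 were shared, and without monogamy male 1 and polygamy females 2 and 3, where the lone polygamy female is assumed to vary like the other groups, it was 24. With the replicate number as a replicate block it was 0, but arrays of different populations share only that number: 2 of 12 arrays correlated best with their own number, and the correlations ran from -0.77 to 0.61. No named transcript lost its sex call with the replicate block of population, and the interaction count stayed at 0. The interaction went from 0 to 1 without dim transcripts, at an adjusted p under 0.1 and with population as a random block, and to 0 to 7 without single arrays. The difference of the sex-biased classes in males was -0.0068 without monogamy male 1, with the sign turned, and up to 0.34 without other single arrays; in females it was 0.28 to 0.72 without single arrays, 0.29 and 0.26 with the quantile normalizations, 0.13 after cyclic loess, 0.32 with classes by adjusted p alone and 0.05 without polygamy females 2 and 3. The correlation of the regime differences was 0.303 to 0.701 without single arrays and 0.244 without monogamy male 1 and polygamy females 2 and 3. Of the alternative values of named transcripts, 255 kept their call and direction and 18 lost the call with the direction kept. Of these losses, 14 were of the 2 transcripts given for regime in females: FBtr0073671 lost its call in 8 of 16 settings and FBtr0112429 in 6 of 15, at differences of -3.68 or larger in size. The fit of the 6 female arrays alone is not in this tally, and both calls were lost there too, since 0 passed. The causes were not tested. Choosing 1 feature per gene, removing listed genes and all gene list alternatives were not run, because 44 identifiers had a name; testing each feature separately is the main setting. Values near the 5th percentile, 4.14 to 4.43 in 11 arrays, leave little room above background, so differences of dim transcripts are limited by it; with that floor no call of a named transcript was lost.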

Other observations

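The test of both sexes below was fixed before its result was seen. Among the 10 transcripts lower in monogamy females, 1 was as far apart in males, which it was singled out for after its values were seen. It stood at 8.67, 8.68 and 9.31 in the monogamy males and at 12.21, 12.55 and 10.95 in the polygamy males, a difference of -3.02, and at -3.10 between the females, so that all 6 monogamy arrays lay below all 6 polygamy arrays. It did not pass the adjusted threshold in males. Over all transcripts, 27 were at least 2-fold apart without overlap in both sexes and in the same direction, 19 higher and 8 lower under monogamy, and 0 in opposite directions. The hypothesis was that a regime difference shared by both sexes would give the real split more such transcripts than each of the other 9. It was not borne out: the split of monogamy 1, monogamy 2 and polygamy 2 from the rest gave 66, although the next highest gave 8.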
